A study of Oryctolagus cuniculus with 3 samples.

How the data were processed

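RNA was measured in the aortic media, the smooth muscle layer of the vessel wall, of 9-month-old male rabbits of the strain JW/CSK. Per the labels' protocols, polyadenylated RNA was enriched with oligo(dT) beads and made into libraries with a TruSeq kit, and the RNA of 5 rabbits was pooled for each of 3 libraries. Samples were grouped by their titles into non-transgenic rabbits on chow, non-transgenic rabbits on a high-cholesterol diet for 20 weeks, and rabbits carrying a mouse PGC-1alpha gene on the same diet. Each group therefore has 1 library, which averages 5 animals and gives no measure of the spread between them. The labels place the chow library on another sequencing lane than the other 2, so the lane and the diet cannot be told apart.

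The deposited values are FPKM (fragments scaled to gene length and to the mapped total), made by the authors and named as such in the file headers. The genome build was OryCun2.0 per the submitters' processing notes. The aligner, the program that made the FPKM values, and any scaling between libraries are not given in the sources used here. The main table holds 15249 rows, of which 15248 are rabbit genes with Ensembl identifiers and 1 is mouse Ppargc1a, placed on a contig of 2394 bp. A row was named by its gene symbol. Where several were joined, LOC names were dropped if others remained, and the last symbol in capitals was taken. The 2043 rows without such a symbol kept a LOC name or their identifier. Of the 15249 rows, 197 were at 0 in every library. Every value column of the table matched a library. The table's other 2 sheets, titled HFD-down and HFD-up, hold 1769 and 9934 rows, of which 1769 and 9933 carry the FPKM values of the main table. In the first, 1048 rows were above chow in the cholesterol library and 721 below, and in the other 4898 were above and 4645 below. The titles do not say which libraries they compare, and the genotype direction of the rows was not checked. Because of this, and because 1094 rows stood in both, these sheets were not used as calls.

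FPKM summed to 943181 in the chow library, 903706 in the non-transgenic cholesterol library and 824460 in the transgenic library, and 13641, 14113 and 14088 rows were above 0. The absolute depth is unknown. The lowest values stand in small whole-number ratios between libraries, which gives the relative depth: the non-transgenic cholesterol library held 1.29 times and the transgenic library 1.26 times the fragments of the chow library. Of 319 low genes compared between the first pair, 78.7% lay within 1% of such a ratio, against 7.52% at a random constant. No counting interval could be made for single genes.

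Differences were taken as log2(FPKM + 1) of 1 library minus another, over 11597 rabbit genes with a mean of at least 1 FPKM over the 3 libraries. The pseudocount of 1 makes the differences of low genes smaller than their true ratios. Genes were counted at a difference of at least 1, which is 2-fold on this scale. With 1 library per group no test was possible, no p-value was computed, and no difference has a replicate check. An exact 0 can be a failed estimate in such a table: 291 of the 11597 genes were listed at 0 in some library, and they enter the counts and the list medians through the pseudocount. Their values are given per library, with no ratio. The list percentiles were also computed without them, in the members and in the random lists.

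Before the data were examined, 37 gene lists were fixed, 12 of cell type markers and 25 of pathways. Each list was described by the median difference of its members, and by how many of 10000 random lists of the same size, matched on mean expression in 20 bins, had a lower median. A list stands apart here when it lies outside the central 95% of its random lists (percentile under 2.5 or over 97.5). This describes these libraries only. Lists with fewer than 5 members among the 11597 genes have values only. Matching was by symbol, so members under an older name are missing: of the nuclear-encoded oxidative phosphorylation list, 48 rows were found for 94 names, some of them aliases. The row of the phagocyte oxidase gene CYBB is shared with XK, and belongs to the macrophage and the NADPH oxidase lists. CTSS belongs to the macrophage and the antigen presentation lists.

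The rule for named genes, also fixed before the data were examined, took PPARGC1A, the 6 largest differences in each direction among genes with a symbol and a mean of at least 5 FPKM, and the 3 members with the largest difference of each of the 8 most extreme lists, for the diet and for the genotype comparison. Because that rule mostly took genes listed at 0, it was repeated after seeing the data among genes above 0 in every library. Other genes, among them those named because a count in a list is 5 or fewer, were chosen after their values were seen. Some genes that the rule took are not reported here.

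The diet and the genotype comparison share the non-transgenic cholesterol library, so its chance values enter them with opposite signs. For the position of the transgenic library, 100 simulations of 3 unchanged libraries were drawn, with noise set so that the variance of the genotype differences was matched, and 100 in which only the diet differences were real. The fraction of the way back to chow, which is the transgenic minus the non-transgenic cholesterol value over the chow minus the non-transgenic cholesterol value, in FPKM, was simulated 1000 times with the same noise. The settings varied, as chosen before the data were examined, were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median centring, upper-quartile scaling, a common total without the 50 most abundant genes, and rows of the same symbol summed. Leaving out genes listed at 0 was added after seeing the data.

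The steps were tested on simulated data built on the chow library of the diet comparison, with 10928 genes and a noise SD of 0.2 on the log2 scale. Of the genes changed 3-fold, 94% were called in the right direction, as were 94% at 4-fold, 100% at 8-fold and 4% at 1.5-fold, and 1 of 10731 unchanged genes was called. That SD is of the noise added to each library, whereas the genotype differences, each between 2 libraries, had an SD of 0.614. The 2 values are therefore on unlike scales, but the self-test noise is the lower on either scale. With the matched noise, 1034 of 11597 genes differed 2-fold between 2 unchanged libraries. The self-test therefore gives no rate of false calls for these data. The matched noise was matched on variance only. Over all genes it gave more 2-fold genes than the genotype comparison itself (197 higher and 244 lower). Without genes listed at 0 it gave fewer (179, against 141 higher and 160 lower). Simulated counts of 2-fold genes are therefore no rate of false calls either. Of 40 unchanged lists of 20 genes, 1 lay outside the central 95% of its random lists, and a list shifted by 0.5 lay at percentile 100. Of 100 genes changed at least 4-fold in the cholesterol library, 100% had that library as the odd one out. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene positions are those of the deposited table. A gene table of another rabbit assembly was not used.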

Results

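Pooled libraries of rabbit aortic media were compared between 3 groups, each from 5 male rabbits: non-transgenic on chow, non-transgenic after 20 weeks of a high-cholesterol diet, and transgenic for mouse PGC-1alpha after the same diet. PGC-1alpha is a transcriptional coactivator that drives mitochondrial biogenesis. The design asks what the diet does to the transcripts of the vessel wall, and how the transgenic animals differ from non-transgenic ones on that diet. Values are FPKM, given for the chow, the non-transgenic cholesterol and the transgenic cholesterol library in that order. There is 1 library per group, so no difference below has a replicate check or a p-value.

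Mouse Ppargc1a (ENSMUSG00000029167, listed at mouse chromosome 5, 51454250 to 51567726, with no build named) was listed at 0 in both non-transgenic libraries and at 12.8 FPKM in the transgenic library, which follows the labels. The rabbit gene PPARGC1A (ENSOCUG00000014668, OryCun2.0 chromosome 2, 14399464 to 14502163) was low throughout, at 1.18, 1.76 and 2.29 FPKM. Its log2 difference was 0.34 for the diet and 0.26 for the genotype, both under 2-fold. Whether reads of the mouse sequence could count toward the rabbit gene is not given in the sources used here.

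With the cholesterol diet, transcripts of macrophages and foam cells were far higher in the media of non-transgenic rabbits, and transcripts of contractile smooth muscle were lower. Of 27 measured macrophage and foam cell markers, 25 were at least 2-fold higher and none was 2-fold lower, with a median log2 difference of 4.37. GPNMB, a glycoprotein of lipid-laden macrophages (chromosome 10, 8328034 to 8362824), stood at 1.54 FPKM on chow and 2034 on the diet, and TREM2, a lipid-sensing receptor of myeloid cells (chromosome 12, 30912169 to 30918630), at 2.10 and 393. MMP12, the macrophage elastase (chromosome 1, 113690095 to 113701956), was listed at 0 on chow and at 1137 on the diet. Of 25 contractile smooth muscle rows, 23 were at least 2-fold lower, with a median of -1.31.

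Among the contractile genes, chosen here after their values were seen, MYH11 (smooth muscle myosin heavy chain) went from 6284 to 1951 FPKM, ACTA2 (smooth muscle actin) from 12462 to 5161 and TAGLN (transgelin) from 7860 to 3888. MYOCD, the coactivator of the contractile program, went from 83.9 to 28.7. CALD1 was lower by less than 2-fold (-0.88). The member that was at least 2-fold higher was 1 of 2 rows named TPM1, at 15.8 and 94.2 FPKM, while the more abundant TPM1 row went from 724 to 266. None of 10000 random lists had a median as low as the contractile list, and all 10000 had a lower median than the macrophage list.

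Lipid handling and lysosomal genes were higher on the diet beside the macrophage markers. In the lysosome and cathepsin list 21 of 25 members were at least 2-fold higher (median 1.84), led by ATP6V0D2, a proton pump subunit (1.45 to 261 FPKM), and the proteases CTSD (115 to 3080) and CTSB (216 to 2550). Of 14 lipid uptake and storage genes 9 were at least 2-fold higher (median 2.09), including the fatty acid carrier FABP5 (4.62 to 325), the lipoprotein-associated phospholipase PLA2G7 (6.97 to 141) and the lipoprotein receptor VLDLR (2.34 to 43.6). Of 13 genes of cholesterol efflux and the sterol-sensing LXR receptors 8 were at least 2-fold higher (median 1.52). Cholesterol synthesis genes went the other way, with 17 of 21 below 0, a median of -0.55 and 4 at least 2-fold lower, including FDFT1 and LSS, while 1 member, the sterol carrier STARD4, was at least 2-fold higher (5.46 to 17.5).

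Immune genes were higher as groups on the diet. All 14 antigen presentation genes were at least 2-fold higher (median 2.23), with HLA-DMA at 1.35 and 119 FPKM, CTSS at 6.86 and 335 and the costimulator CD86 at 0.29 and 32.1. Of 24 cytokine, chemokine and adhesion genes 19 were at least 2-fold higher (median 2.07), with the interleukin-1 antagonist IL1RN at 0.16 and 33.7 and the endothelial adhesion molecule VCAM1 at 2.63 and 59.2. In that list CXCL12 was the member at least 2-fold lower, listed at 0 in both cholesterol libraries. Of 23 interferon response genes 14 were at least 2-fold higher (median 1.61), with OASL at 0.36 and 15.1, OAS2 at 2.03 and 33.4 and MX2 at 2.85 and 38.5. Complement had 9 of 14 (median 1.46), senescence and cell death 8 of 12 (median 1.33), and the phagocyte NADPH oxidase list 4 of 5 (median 4.29), including RAC2 and NCF4.

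Proliferation and matrix genes were also higher on the diet. Of 26 cell cycle genes 25 were at least 2-fold higher (median 2.39), such as MKI67 at 0.08 and 11.2 FPKM, CCNB2 at 0.27 and 12.7 and RRM2 at 0.43 and 13.7. Of 23 genes of fibrillar collagen and elastic matrix 11 were at least 2-fold higher and none was 2-fold lower (median 0.82). The metalloproteinase and inhibitor list had 5 of 11 at least 2-fold higher (MMP9, MMP14, TIMP1, MMP1 and MMP3, median 0.96). MMP1 and MMP3 are listed at 0 on chow. Without them its median was 0.60 at percentile 95.6, and the list did not stand apart. Glycolysis had 10 of 20 at least 2-fold higher and 1, PFKP, lower (median 0.97). The antioxidant list had 5 of 18 higher (HMOX1, GPX1, CAT, TXNRD1 and SRXN1, median 0.50), with HMOX1, the haem oxygenase, at 4.28 and 94.7 FPKM.

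Mitochondrial transcripts split by genome. Of 13 genes encoded in mitochondrial DNA 9 were at least 2-fold higher on the diet (median 2.01), with MT-ATP8 at 3537 and 35838 FPKM, cytochrome b (CYTB) at 366 and 3495 and MT-ND3 at 788 and 5344. MT-ATP8 overlaps MT-ATP6, so the reads of these genes cannot be separated in the overlap. The 47 nuclear genes of oxidative phosphorylation had a median of 0.09, fatty acid oxidation 0.04 over 25 genes, the tricarboxylic acid cycle 0.08 over 17, and the partners of PGC-1alpha in mitochondrial biogenesis 0.00 over 17. None of these last 4 lists stood apart from random lists.

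Markers of other cell types did not move together. Endothelial markers had a median of 0.93, with 3 of 13 at least 2-fold higher (VWF, EMCN and ROBO4) and 1 lower (ESAM). Schwann cell and nerve markers had a median of -1.11 with 4 of 7 at least 2-fold lower, including S100B (8.14 and listed at 0) and SOX10, and striated muscle genes -1.71 with 5 of 5 lower. Cartilage and bone genes had a median of -0.50 with 1 of 11 lower (SOST) and 2 higher (CYTL1 and SPP1), and without 1 gene listed at 0 this list lay at percentile 2.93 and did not stand apart. SPP1, osteopontin, which macrophages also make, stood at 22.1 and 1740 FPKM. Immediate early and heat shock genes, a sign of tissue handling, had a median of 0.56 with 4 of 19 at least 2-fold higher (ATF3, FOSB, EGR2 and NR4A1) and 1 lower (HSPB1). Lists that did not stand apart were adventitial fibroblast (-0.40), adipocyte (-0.20), T cell (0.29), unfolded protein response (0.44), calcification inhibitors and phosphate (0.61), autophagy (0.02) and ribosomal proteins (-0.11). B cell and plasma cell markers (median 3.50 over 4 genes), neutrophil and mast cell markers (2.54 over 3, all listed at 0 on chow) and the erythroid gene ALAS2 (0.01) were too few for a percentile.

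Over all 11597 genes, 1846 were at least 2-fold higher on the diet and 811 lower, of which 186 and 58 were listed at 0 in 1 of the libraries compared, and 829 and 85 differed at least 4-fold. The largest differences by the fixed rule were mostly such genes. APRT (listed at 0 and 1290 FPKM), LINC00116 (0 and 435) and TOMM5 (0 and 281) were higher, beside MMP12, GPNMB and the lectin LGALS9 (0.27 and 248). NDUFB7 (3244 and 0), C14orf2 (445 and 0), PI16 (411 and 0), SPTSSA (374 and 0), MT3 (248 and 0) and CXCL12 (73.8 and 0) were lower. Among genes above 0 in every library, MLANA (0.36 and 212) and the protease CTSE (0.07 and 118) were also among the 6 highest differences. Among the 6 lowest were PFN2 (18.4 and 1.30), the histamine receptor HRH1 (10.5 and 0.37), PTGR1 (48.5 and 5.60), C1QTNF3 (21.8 and 2.11) and the ATP-gated channel P2RX1 (59.3 and 7.33). Of the 34 lists with a percentile, 18 stood above and 5 below their random lists, and 21 in all did so without genes listed at 0. With a pseudocount of 5 the counts were 1118 higher and 413 lower. Simulated unchanged libraries gave 1034 genes with a 2-fold diet difference in either direction, against 2657 observed. Without genes listed at 0 they gave 179, against 2404. The simulated noise matches the genotype differences in variance only. It does not reproduce their number of 2-fold genes (197 higher and 244 lower, or 141 and 160 without genes listed at 0). The simulated counts are therefore no rate of false calls.

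**Figure D1:**
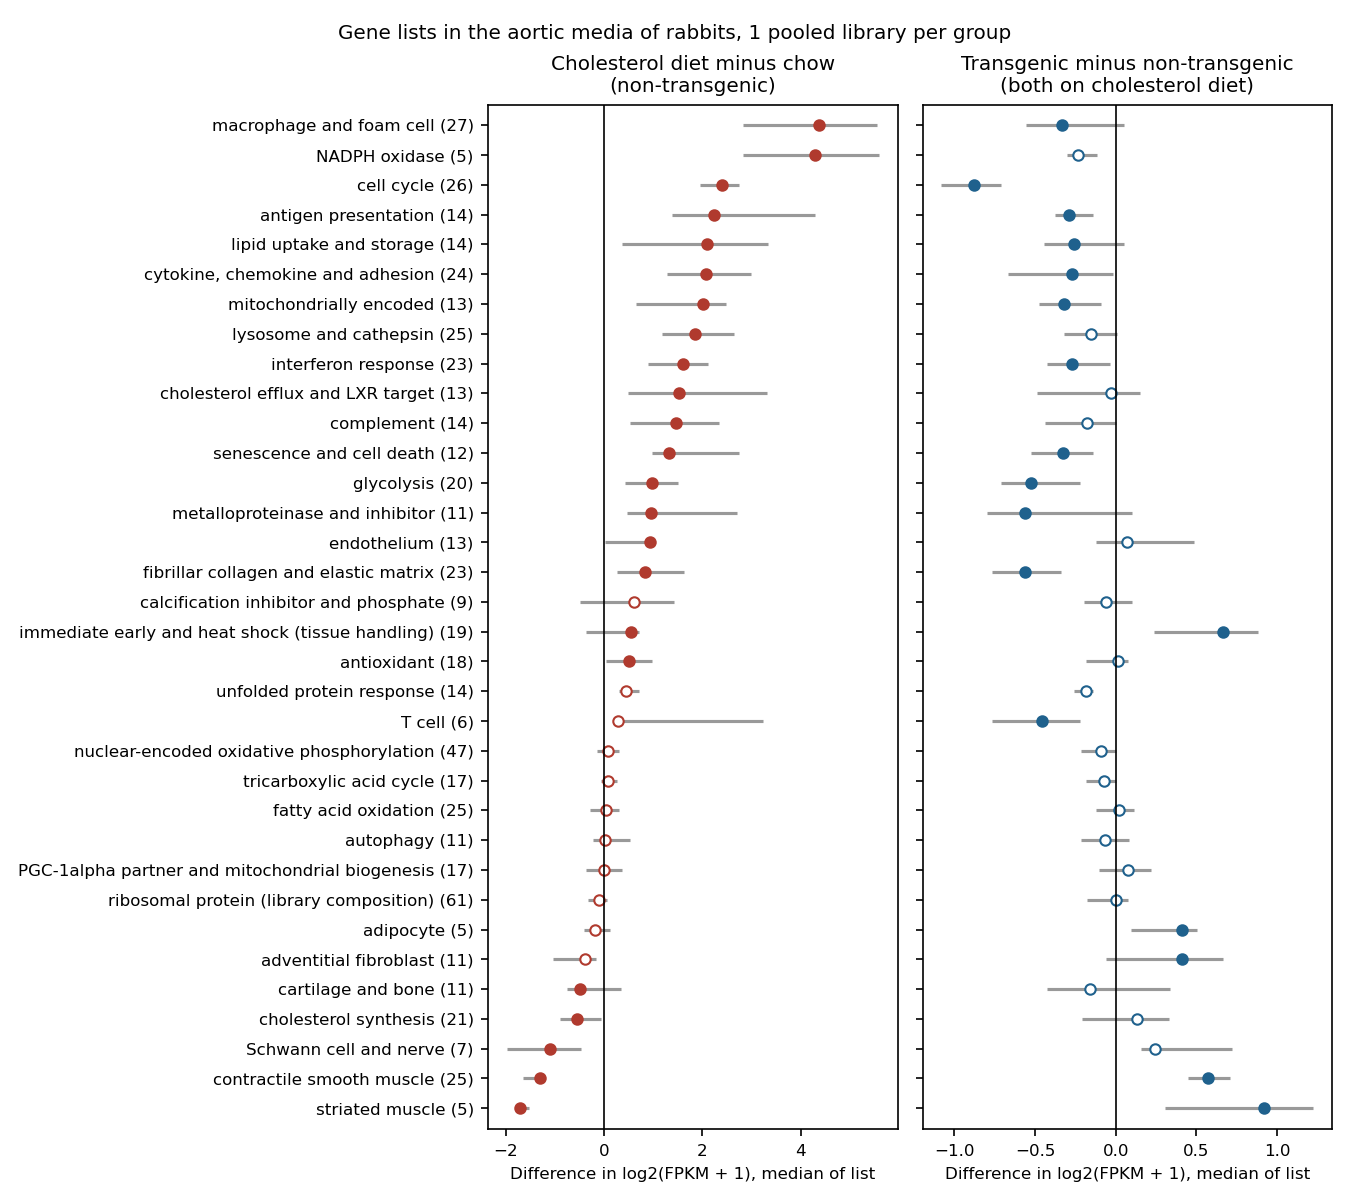
Median difference in log2(FPKM + 1) of 34 gene lists (number of measured members in brackets) for the diet and for the genotype comparison. Points are medians, grey lines the middle 50% of members, and filled points lists outside the central 95% of 10000 random lists. The macrophage list lies at 4.37 and -0.33, and the contractile smooth muscle list at -1.31 and 0.57. The horizontal scales of the panels differ.

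Between transgenic and non-transgenic rabbits on the cholesterol diet, contractile smooth muscle genes were higher in the transgenic library and cell cycle, matrix and glycolysis genes were lower. Of 25 contractile rows 24 were above 0 (median 0.57), none of them by 2-fold. LMOD1, an actin nucleator of smooth muscle (chromosome 16, 69647625 to 69693493), stood at 653, 179 and 340 FPKM in the chow, non-transgenic and transgenic libraries, the intermediate filament protein SYNM at 106, 30.6 and 56.4, and SMTN (smoothelin) at 375, 123 and 220. Of 26 cell cycle genes 25 were below 0 and 10 at least 2-fold lower (median -0.88), with CCNB1 at 0.28, 8.19 and 2.35, KIF20A at 0.42, 9.53 and 3.14 and CCNB2 at 0.27, 12.7 and 4.45.

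Matrix genes were lower in the transgenic library, with 22 of 23 below 0 and 5 at least 2-fold lower (CTHRC1, COL8A1, THBS1, POSTN and LOX, median -0.56). CTHRC1, a secreted protein of activated fibroblasts and smooth muscle (chromosome 3, 118774867 to 118791581), stood at 0.28, 35.0 and 6.30 FPKM, the collagen COL8A1 at 14.5, 200 and 73.9, and THBS1 (thrombospondin) at 5.75, 51.0 and 20.3. The metalloproteinase and inhibitor list had a median of -0.56 over 11 genes, but -0.26 at percentile 3.21 without MMP1 and MMP3, where it did not stand apart. Its members with the largest differences were MMP1 at 0, 9.91 and 1.007, MMP3 at 0, 5.73 and 0.66 and the inhibitor TIMP1 at 73.6, 476 and 268. Of 20 glycolysis rows 17 were below 0 (median -0.53), with ENO2 at 0.82, 5.22 and 1.30, the glucose transporter SLC2A3 at 3.75, 43.1 and 22.1 and LDHA at 45.4, 206 and 112.

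Macrophage and foam cell markers were lower by a small amount, with 20 of 27 below 0 and a median of -0.33, and their members went both ways. LYZ (lysozyme) stood at 4.90, 5.88 and 0.50 FPKM, the scavenger receptor MSR1 at 0.38, 33.7 and 8.44, and MMP12 at 0, 1137 and 569, while GPNMB differed little (2034 and 2010). The members at least 2-fold higher, named after their values were seen, encode subunits of complement C1q: C1QB at 5.39, 27.1 and 96.0, and C1QC at 23.0, 167 and 450.

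Immediate early genes were higher in the transgenic library, with 16 of 19 immediate early and heat shock genes above 0 and 4 at least 2-fold higher (FOSB, NR4A1, EGR1 and FOS, median 0.67). FOSB stood at 4.01, 13.7 and 108 FPKM, the nuclear receptor NR4A1 at 12.1, 26.5 and 152, and EGR1 at 85.9, 128 and 407. These genes respond within minutes to handling of tissue as well as to stimuli in the animal. Of the striated muscle genes 4 of 5 were above 0 (median 0.92), with ACTA1 at 1.98, 0.21 and 1.90, TNNT2 at 197, 56.3 and 133 and CKM at 57.4, 19.1 and 37.0. Adventitial fibroblast (0.41 over 11 genes) and adipocyte markers (0.41 over 5) also stood above their random lists.

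Further lists below their random lists were T cell (-0.45 over 6 genes), senescence and cell death (-0.33), mitochondrially encoded genes (-0.32, 10 of 13 below 0), antigen presentation (-0.29), cytokine, chemokine and adhesion (-0.27), interferon response (-0.27) and lipid uptake and storage (-0.26). Of the lists nearest to the known targets of PGC-1alpha, the mitochondrially encoded genes thus stood apart as lower, and 5 lists of nuclear genes did not stand apart. Nuclear-encoded oxidative phosphorylation had a median of -0.09 with 1 of 47 genes at least 2-fold higher (COX7A2, listed at 0 in the non-transgenic cholesterol library), fatty acid oxidation 0.02, the tricarboxylic acid cycle -0.07, the partners of PGC-1alpha 0.07 and the antioxidant list 0.01. At percentiles of 11.98, 71.27, 30.17, 82.62 and 67.47, all 5 lay within their random lists.

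The other lists that did not stand apart were lysosome and cathepsin (-0.15), complement (-0.18), NADPH oxidase (-0.23), cholesterol efflux and LXR targets (-0.03), cholesterol synthesis (0.13), endothelium (0.07), Schwann cell and nerve (0.24), cartilage and bone (-0.16), unfolded protein response (-0.18), calcification inhibitors and phosphate (-0.06), autophagy (-0.07) and ribosomal proteins (0.00). B cell and plasma cell markers had a median of -0.57 over 4 genes, neutrophil and mast cell markers 0.99 over 3, and the erythroid gene ALAS2 stood at 1.14, 1.16 and 3.35 FPKM.

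Over all 11597 genes, 197 were at least 2-fold higher and 244 lower in the transgenic library, of which 53 and 49 were listed at 0 in 1 of the libraries compared. The largest differences by the fixed rule were DEFB1 (0, 0 and 901 FPKM), C14orf2 (445, 0 and 602), MRPL36 (0, 0 and 300.2), PI16 (411, 0 and 298), SDHAF4 (7.95, 0 and 59.6) and NUPR1 (27.8, 0 and 49.0) on the higher side. On the lower side they were C1orf21 (0, 78.4 and 0), TMEM238 (0, 56.0 and 0), SMIM10L1 (82.6, 56.0 and 0), C4orf32 (37.2, 43.6 and 0), RPL17 (278, 580 and 23.7) and GCHFR (0, 19.2 and 0). RPL17, RPS27L and other ribosomal protein genes have near-identical copies in mammalian genomes, so their values are uncertain. Several genes listed at 0 have short loci, such as DEFB1, MRPL36, TMEM238 and SMIM10L1, and their values may rest on few fragments.

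Among genes above 0 in every library, the 6 highest differences were FOSB, PDILT (17.8, 3.47 and 30.5 FPKM), RPS27L (9.88, 11.01 and 65.9), NR4A1, the methionine sulfoxide reductase MSRB1 (5.63, 0.77 and 8.68) and LSM5 (79.0, 24.1 and 133). The 6 lowest were RPL17, the acute phase protein SAA3 (7.14, 389 and 66.0), SNRPF (16.5, 11.5 and 1.19), PSAT1 of serine synthesis (0.21, 16.8 and 2.23), SERP1 (133, 303 and 56.2) and CTHRC1. Of the 34 lists, 5 stood above and 12 below their random lists, and 16 in all did so without genes listed at 0. The counts depend on the treatment of low values: with a pseudocount of 0.1 they were 323 and 360, and with a pseudocount of 5 they were 75 and 96. The simulated noise was matched to the variance of the genotype differences themselves, but not to their number of 2-fold genes. Between 2 unchanged libraries it gave 1034 such genes over all genes, more than observed. Without genes listed at 0 it gave 179, fewer than the 141 higher and 160 lower observed. It therefore gives no separate expectation for the genotype counts.

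**Figure D2:**
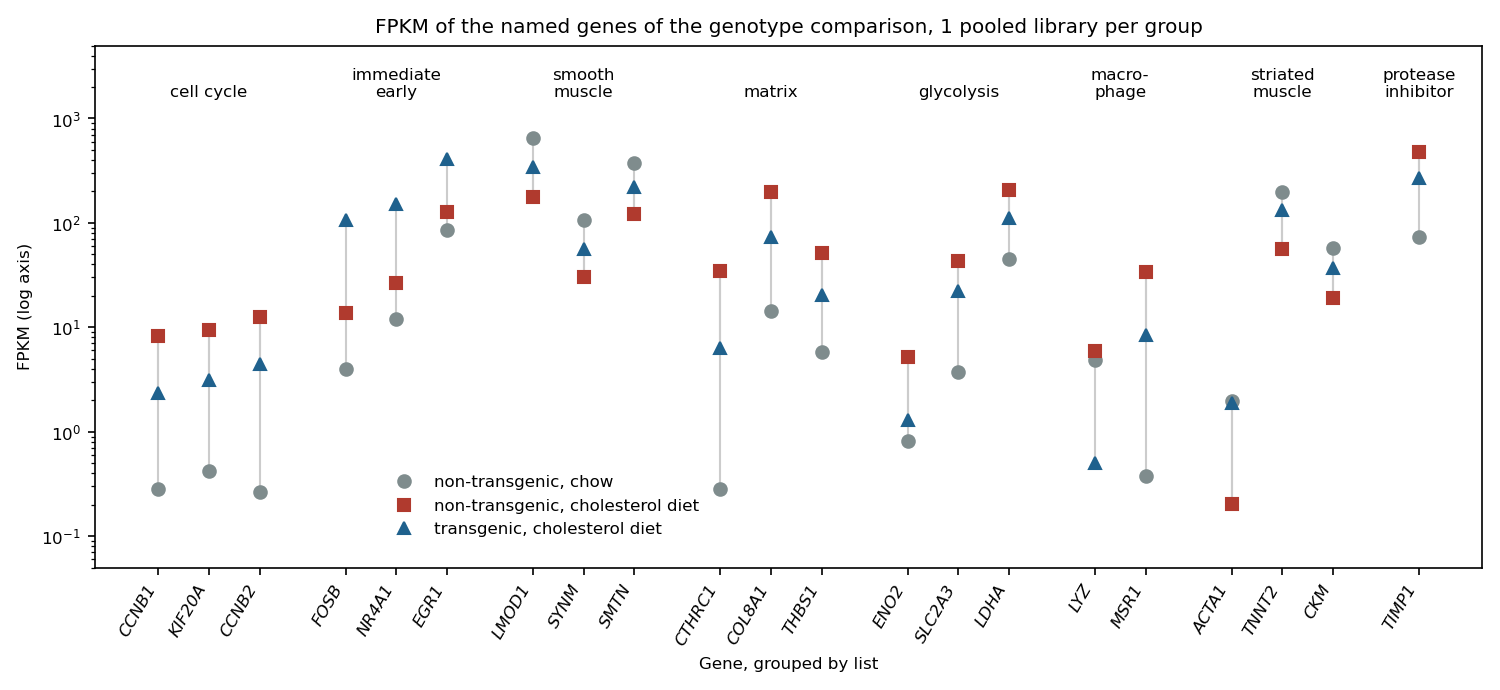
FPKM on a log axis of the named members of 8 gene lists in the 3 libraries, for genes above 0 in each. Each column is a gene, and the marks are the chow, the non-transgenic cholesterol and the transgenic cholesterol library. LMOD1 stands at 653, 179 and 340 FPKM, CCNB2 at 0.27, 12.7 and 4.45, and FOSB at 4.01, 13.7 and 108.

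The transgenic library differs from the chow library in both diet and genotype, and was compared with it to place the 3 libraries. Contractile smooth muscle genes were below chow in the transgenic library (median -0.87, with 24 of 25 rows below 0 and 1, PLN, at least 2-fold lower), and macrophage markers were above it (median 4.04, 25 of 27 at least 2-fold higher). Cell cycle genes had a median of 1.59, lysosome and cathepsin genes 1.70, and matrix genes 0.21, which did not stand apart. In all, 1457 genes were at least 2-fold higher than on chow and 293 lower. With a pseudocount of 5 these counts were 817 and 138, and with a mean of at least 5 FPKM 193 were lower. Of the 34 lists, 18 stood above and 4 below their random lists.

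Of the 1846 genes at least 2-fold higher on the diet in non-transgenic rabbits, 72.7% were also at least 2-fold above chow in the transgenic library, and of the 811 lower genes 26.3% were at least 2-fold below it. Simulated unchanged libraries gave 30.0% and 29.9%, and simulations in which only the diet differences were real 79.1% and 63.6%. Without genes listed at 0 the shares were 72.5% and 23.6%, against 14.1% and 14.6% in unchanged libraries and 83.1% and 68.7% with only the diet differences real. Among 2898 genes that differed 2-fold between any pair of libraries, the odd one out was the chow library for 2243, the non-transgenic cholesterol library for 511 and the transgenic library for 144, against 719, 721 and 723 in simulated unchanged libraries and 2727, 456 and 1027 with only the diet differences real. Without genes listed at 0 these counts were 2073, 432 and 102, against 155, 154 and 156 in unchanged libraries and 2703, 184 and 327 with only the diet differences real, so the count of the non-transgenic cholesterol library lay below that of unchanged libraries over all genes, and above it here. Over all genes, 2163 genes differed between any pair in unchanged libraries and 4210 with only the diet differences real, against 2898 observed. Without genes listed at 0 these totals were 464 and 3215, against 2607. The simulated counts of the odd one out thus rest on other totals than the observed ones. Of the 2657 genes with a 2-fold diet difference, 2349 (88.4%) had a genotype difference of the opposite sign. Simulated unchanged libraries gave 85.1%, and those with only the diet differences real 66.5%, with a central 95% range of 64.7% to 68.2%. The share was 90.3% without genes listed at 0, against 92.7% and 63.9%.

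Across genes, which are not independent replicates, the diet and genotype differences had a correlation of -0.50, as in simulated unchanged libraries (-0.50), and a covariance of -0.382 against -0.189 there. With only the diet differences real they were -0.25 (central 95% range -0.27 to -0.23) and -0.188. Without genes listed at 0 the correlation was -0.58 against -0.50 in unchanged libraries, and the covariance -0.247 against -0.0815. With only the diet differences real these were -0.19 and -0.0813. Of the genes at least 2-fold higher on the diet, 186 were at least 2-fold lower in the transgenic library, where independent lists would share 38.8 and simulated unchanged libraries shared 158.8. Of those lower on the diet 112 were higher in it, against 13.8 and 156.9. In the same direction the shared genes were 7, against 31.4 and 8.54, and 3, against 17.1 and 9.44. With only the diet differences real these 2 counts were 33.9 and 22.9. With only the diet differences real, the counts in opposite directions were 197.9 (central 95% range 174.5 to 219.1) and 80.8 (66 to 94.5). The 186 observed lay within the first range. However, that simulation had 4210 genes changed between any pair of libraries, against 2898 observed. It therefore cannot decide whether 186 is an excess over all genes. The simulated libraries share the cholesterol library between the comparisons in the same way. The counts for independent lists use the observed list sizes, whereas the simulated lists have sizes of their own. Unchanged libraries had 1034 genes with a 2-fold diet difference, against 2657 observed, so the shared counts are not like for like. Among genes above 0 in every library, 118 and 82 genes were shared in opposite directions, against 12.8 and 12.7 in simulated unchanged libraries, and 40.1 and 12.5 with only the diet differences real. In the same direction 5 and 0 of them were shared, against 4.05 and 2.52 with only the diet differences real.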

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

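Apart from leaving out genes listed at 0, which was chosen after seeing the data, the alternatives were chosen before the data were examined. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Of 906 list medians under an alternative, 822 moved by less than the SD of their random lists, 83 moved by more and 1 reversed: the cartilage and bone median for the diet was 0.075 with no filter on low values, where more genes of low level enter the list. Of 768 log2 differences of named genes, 666 moved by no more than the scaled median absolute deviation of all genes' differences in that comparison (0.691 for the diet, 0.310 for the genotype) and 102 by more, 59 of them with a pseudocount of 5 and 40 with one of 0.1. The share of diet genes with the opposite sign in the genotype comparison (88.4%, 95% exact binomial interval 87.1 to 89.6) stayed within its interval under 6 of 9 alternatives, and was 90.1% with a pseudocount of 5, 89.9% with a mean of at least 5 FPKM and 90.3% without genes listed at 0. That interval takes genes as independent and measures no spread between rabbits, so it serves here only to mark the size of a shift. The 3 scalings moved the median of all genes by less than 0.1, and each kept the counts of 2-fold genes within 1.5 times.

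A pseudocount of 5, which shrinks differences of low genes by construction, gave 1118 genes higher and 413 lower for the diet, 75 and 96 for the genotype, and 817 and 138 for transgenic against chow, with 1351, 228 and 63 genes for which the chow, non-transgenic cholesterol and transgenic library was the odd one out. A pseudocount of 0.1 gave 323 genes higher for the genotype. A mean of at least 5 FPKM tests fewer genes, and gave 117 higher and 118 lower for the genotype, 193 lower for transgenic against chow, and 303 and 75 with the non-transgenic cholesterol and the transgenic library as the odd one out. Without genes listed at 0, 160 genes were lower for the genotype, the metalloproteinase list no longer stood apart in any comparison, and the cartilage and bone list did not for the diet, while the matrix list then did for transgenic against chow. An analysis of read counts was not run, since the table used here holds none. One of the authors' own calls was not run either, since the titles of the HFD-down and HFD-up sheets do not say which libraries they compare. The absolute depth is unknown, which limits genes near 0, such as the cell cycle genes on chow.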

Other observations

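Several genes, chosen after their values were seen, were higher on the cholesterol diet and lower in the transgenic library. Among them, PHGDH stood at 5.44, 20.0 and 4.20 FPKM in the chow, non-transgenic cholesterol and transgenic library, PSAT1 at 0.21, 16.8 and 2.23, SHMT2 at 1.06, 16.6 and 5.29 and MTHFD2 at 10.4, 69.9 and 30.9. PSPH did not follow (1.93, 2.92 and 3.69), and the annotated pathway of glycine, serine and threonine metabolism as a whole lay within its random lists, with a median of 0.27 for the diet and 0.02 for the genotype over 24 genes. One carbon pool by folate (0.45 and -0.22 over 17 genes) lay outside its random lists for the genotype only. The stress-responsive genes TRIB3 (0.29, 8.33 and 2.31) and SESN2 (0.97, 13.4 and 5.51) and the angiogenic factor VEGFA (7.21, 51.9 and 19.8) followed the same order. So did IGJ, the immunoglobulin joining chain of the fixed B cell and plasma cell list, at 5.52, 181 and 42.3.

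Other genes chosen after their values were seen were higher on the diet and within 2-fold by genotype: the ferritin chains FTL (509, 7726 and 5924 FPKM) and FTH1 (2757, 18950 and 15928), the chitinase CHIT1 of lipid-laden macrophages (0.07, 85.0 and 60.9) and the iron uptake receptor TFRC (11.7, 55.8 and 46.5). Pathway annotations in the deposited table were also compared after the fixed lists, over 256 pathways with at least 10 measured genes and against 2000 random lists each. Vascular smooth muscle contraction had a median of -0.43 for the diet and 0.19 for the genotype over 65 genes, and lysosome 1.28 and -0.15 over 88. For the genotype, the annotated lysosome, steroid biosynthesis (median 0.29 over 13 genes), complement (-0.18 over 23) and protein processing (-0.11 over 113) pathways lay outside their random lists, while the fixed lists of lysosome, cholesterol synthesis, complement and unfolded protein response did not. Conversely, the annotated antigen presentation (-0.10 over 40) and matrix receptor (-0.06 over 53) pathways lay within theirs, unlike the fixed antigen presentation and matrix lists. The annotated oxidative phosphorylation pathway, which in this annotation also takes in mitochondrially encoded genes and proton pumps such as ATP6V0D2, had a median of 0.28 and -0.15 over 85 genes and lay outside its random lists in both comparisons, unlike the fixed nuclear list.

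All tests of explanations below were chosen after the values had been seen. The first pattern is the opposite movement of macrophage and contractile transcripts on the diet. If incoming macrophages only diluted the resident cells, every resident type would be lower alike. The endothelial median exceeded the contractile median by 2.24 (95% interval 1.31 to 2.58 over resampled genes), and the adventitial median exceeded it by 0.91 (0.20 to 1.39). These intervals take genes as independent and measure no spread between rabbits. The share of endothelial and adventitial cells in dissected media also depends on the dissection, so these medians cannot decide on dilution of smooth muscle. Schwann cell and nerve (-1.11) and striated muscle genes (-1.71) lay near the contractile median (-1.31), as dilution would give. The intervals of their differences from it were -1.43 to 1.23 and -0.64 to 0.12. Whether the 5 striated muscle genes stem from cells other than smooth muscle was not tested, so that list may be no separate resident type. For adipocyte markers (-0.20) the interval also included 0 (-0.14 to 3.16). The scaling of the libraries is argued against by the contractile median, which was -1.33 at its nearest to 0 under 3 scalings. A change within smooth muscle cells on the diet, a larger share of macrophages as part or all of the cause, and a difference in how the layers were dissected may each contribute and were not told apart. The sequencing lane differs with the diet and cannot be told apart from it.

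The second pattern is the position of the transgenic library between the other 2. Noise of single genes in the shared cholesterol library could give opposite signs, but if independent between genes it would average out over lists fixed in advance. For the genotype, 17 of 34 lists (16 without genes listed at 0) lay outside the central range of random lists, where 1.7 are expected from such noise. This count takes any genotype difference, also where the transgenic library does not lie between. Against chow, the medians of immediate early and heat shock genes were 0.56 in the non-transgenic cholesterol and 0.60 in the transgenic library. Those of adipocyte markers were -0.20 and 0.62, and those of T cell markers 0.29 and -0.09. A single fraction of less affected tissue in the transgenic pool, as the whole cause, would give lists about the same fraction of the way back to chow. That fraction was 0.13 for macrophage genes and 0.59 for cell cycle genes, a difference of 0.466 (95% interval 0.289 to 0.605 over resampled genes). These lists were picked after their values were seen, and noise in the shared library makes such fractions positive. In 1000 simulations with noise and 1 true fraction of 0.23, set to give the 0.31 observed over 2404 genes, none had so large a difference between these lists. The cell cycle fraction lay above its simulated range (0.24 to 0.50) and the macrophage fraction below its range (0.25 to 0.45). However, the largest difference between any pair of 15 lists, observed at 0.526, was reached in 55 of the 1000 simulations. When the observed fractions of the members were shuffled between these lists, 22 of 10000 shuffles reached that difference. The interval, the simulations and the shuffles also take genes as independent, so they do not decide whether 1 fraction is the whole cause. With only the diet differences real, the median over the 2404 genes was 0.10, and macrophage genes gave 0.16, so their 0.13 is not more than noise gives. Such a fraction as part or all of the cause remains open. An effect of the transgene, and a chance difference between the 2 pools of 5 rabbits in lesion extent or in handling, to which the higher immediate early genes may belong, remain open and untested.

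The third pattern is the genes listed at 0 in a library with at least 20 FPKM in another. Of 84 such genes, 56.0% (95% exact binomial interval 44.7 to 66.8) spanned less than 1 kb in the table, against 8.39% of 5054 genes at 20 FPKM or more that were above 0 everywhere. Failed estimates at short loci would give this, but so would values that rest on few fragments, where a 0 may be sampling. DEFB1 and MRPL36 stood at 900.582 and 300.194 FPKM in the transgenic library, a whole-number ratio. TMEM238 and SMIM10L1 shared the value 55.9521 in the non-transgenic cholesterol library. The 2 sources cannot be told apart here, for NDUFB7 (3244, 0 and 0 FPKM) among others. The remaining genes span 1 kb or more, and some, such as MMP12, are macrophage genes that may be absent from the chow library, which was not tested.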
